A study of Arabidopsis thaliana with 12 samples.

How the data were processed

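Total RNA from roots of hydroponically grown Arabidopsis thaliana Col-0 plants was measured on 12 Affymetrix arrays, 3 for each of 4 groups. The groups were control, arsenic (250 µM arsenate), hypoxia and combination (arsenate in hypoxic medium), all harvested after 7 days of treatment at a plant age of 39 days. The series text describes the replicates of a group as fully independent, so the replicate numbers were not taken as pairs. Per the labels, RNA was extracted by lithium chloride precipitation and prepared for hybridisation with the GeneChip WT PLUS kit.

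The deposited values are log2 signals per probe set, which the authors made with RMA (background correction, quantile normalization between arrays and summary over probes). The labels name Affymetrix Expression Console 1.4 and 1.4.1 and Transcriptome Analysis Console 3.1. The values were used as deposited, with no further filter, transformation or correction. Signals per probe and raw images were not used, and the precision depends on the number of arrays and the spread between them.

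The table had 38408 rows. The probe annotation listed 17481 of them and left 20927 unlisted, 759 listed rows named several genes and 16722 named 1 gene. Of the last, 16574 were matched by gene identifier to a RefSeq gene table (assembly TAIR10.1), used for names alone, and 148 were not. Where a gene had several rows (146 genes), the row with the highest mean over all arrays was used, which left 16550 genes, 1805 of them with a symbol other than a locus code. The genome build behind the array is not stated, so no coordinates are given.

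All arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group means as coefficients), since 3 arrays per group give few degrees of freedom. The 5 pairwise comparisons and the interaction (combination minus arsenic minus hypoxia plus control) were tested two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05 on the adjusted p. In simulated data with 50 genes planted at each size among 16550, the test of hypoxia against control recovered 8, 35, 48 and 49 of 50 genes with changes of 1.5-fold, 2-fold, 4-fold and 8-fold and called 6 of 16350 unchanged genes, and the interaction recovered 1, 11, 46 and 49 and called 9.

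The groups, comparisons, alternatives, tests and 20 gene lists were fixed before the data were examined, except where stated. The lists covered the core hypoxia response, phosphate starvation, sulfate assimilation with glutathione and phytochelatin, arsenic handling, glutathione S-transferases, antioxidant enzymes and oxidative stress markers, iron deficiency, nitrogen uptake, root hairs, cell division, jasmonate, salicylate and camalexin, abscisic acid and dehydration, ethylene, chaperones, the Casparian strip and suberin, xylem, aquaporins, green tissue and reference genes. Of their 384 entries 47 were measured. The 7 lists with 3 or more measured members were tested as sets, and 5 lists had no member. Sets were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation. Their p-values were adjusted within a comparison, separately over the 7 tested fixed lists, the 29 symbol families and the lists formed later. Adjusted p-values of different kinds of sets are thus not on 1 scale. With the estimate, the calls of the core hypoxia list (hypoxia against control, combination against control and combination against arsenic) and of the iron list (hypoxia against control) held, and the other 10 calls of fixed lists did not. The estimate for the iron list was 0.00302, below the preset, yet its calls in the combination against control and the interaction were lost. A lost call thus need not mean that the members of a list were correlated. Counts of members that passed are given over all genes tested and adjusted over the list alone, where a list of 1 measured gene has nothing to adjust. A further 29 families of at least 5 genes were formed from gene symbols once the annotation had been read and before any value was tested.

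Genes were named by a rule. For the comparisons with control, it took the 6 largest rises and 6 largest falls among genes with a symbol that passed and whose treated arrays did not overlap the control arrays, and up to 3 members of each list by size of change. For the other comparisons it took 4 and 4, without the overlap condition for the interaction, and up to 2 members of each list. HAC1 and GSTU25, the measured ones of 20 genes to be named in any case, were added throughout. Some genes that the rule allows were left out for length, and other list members named to account for a small count were chosen after their values were seen. Several named genes have close paralogs (beta-glucosidases, glutathione S-transferases, xyloglucan endotransglucosylase/hydrolases), whose transcripts can bind each other's probes.

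Changes against the same controls were set beside 100 simulations of unchanged groups with the fitted spread, since 3 controls cannot be divided. The change with 1 treatment in the presence of the other, per unit of its change alone, was the slope across genes of differences that share no array, corrected for noise, with a jackknife SE over arrays. These slopes were chosen after the data were seen.

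The alternatives were fitting the arrays compared alone, the replicate number as a block, arrays re-centred on their median, a second quantile normalization, leaving out the 33.3% of genes with the lowest mean, an intensity trend with robust hyperparameters, array weights, the mean of all rows of a gene, every row of the table, a minimum change of 2-fold, an estimated correlation for sets, and leaving out each array in turn. For every pairwise comparison the 10 splits of its 6 arrays were counted, and for the interaction 100 drawn splits. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Rows with no gene of their own took no part in the tests of genes.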

Results

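Roots of Arabidopsis thaliana Col-0 plants were profiled on 12 Affymetrix arrays after 7 days of treatment in hydroponic culture, when the plants were 39 days old. The arrays fell into 4 groups of 3, each from independent biological replicates, namely untreated control roots, roots given 250 µM arsenate (arsenic), roots in hypoxic nutrient medium (hypoxia) and roots given both (combination). The oxygen content of the hypoxic medium was not stated. The deposited table held 38408 rows of log2 signal, of which 16722 could be paired with 1 gene, and 16550 genes were tested. The named genes left out much of the known biology, since 47 of the 384 entries of the lists fixed before the data were examined had a row of their own. ADH1, PDC1, IRT1 and every member of the phosphate starvation, cell division, salicylate and camalexin, Casparian strip and suberin, and aquaporin lists had none. The median signal of the arrays ran from 4.72 to 4.99. Arrays of the same group correlated across genes at r from 0.972 to 0.991, and arrays of different groups at r from 0.924 to 0.982. The highest value between groups joined hypoxia array 1 to combination array 1. Genes are not independent replicates, so these correlations carry no test. The first 2 principal components held 43.9% and 22.6% of the variance. Changes below are log2 differences between group means of 3 arrays with the SE of the fitted difference. Genes are ranked below only among the 1805 with a symbol other than a locus code, and among those whose treated arrays all lay above or all below the arrays compared.

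**Figure D1:**
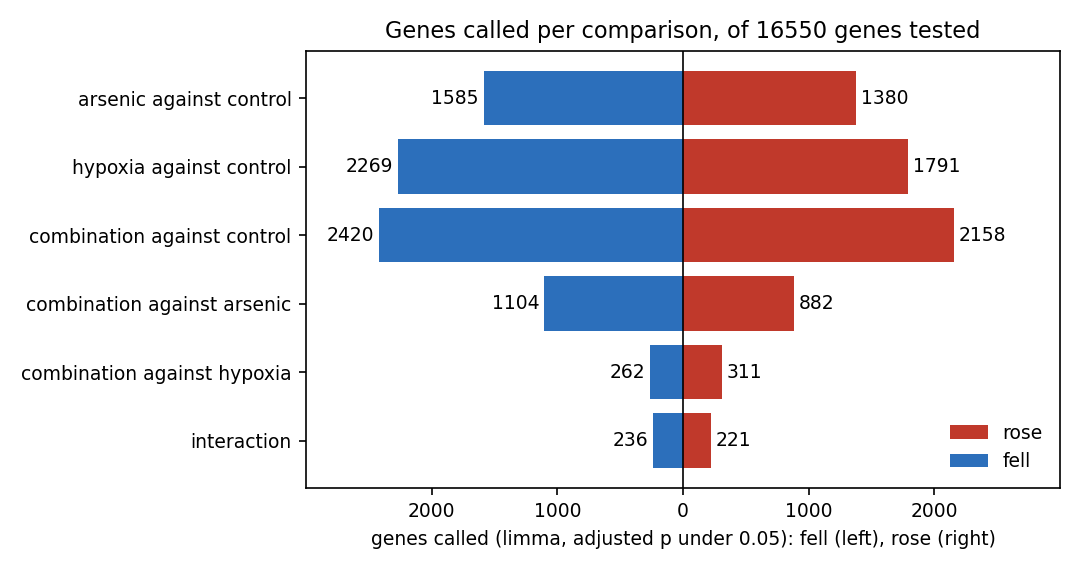
Number of genes, of 16550 tested, that rose (red, to the right) or fell (blue, to the left) in each comparison at an adjusted p under 0.05 (limma). Bars are counts on a linear axis that starts at 0, and run from 457 genes in the interaction (221 and 236) to 4578 in the combination against control (2158 and 2420).

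Arsenate alone was compared with the control to show what arsenate did to roots that were not hypoxic. UPOX (AT2G21640), a mitochondrial protein induced by oxidative stress, rose 37.1-fold (log2 change 5.21, SE 0.28, adjusted p = 3.91e-07). GSTU25 (AT1G17180), a tau-class glutathione S-transferase of the kind that conjugates toxic compounds, rose 19.3-fold (4.27, SE 0.54, adjusted p = 0.000192). The stress-responsive transcription factor DREB2C (AT2G40340) rose by 3.70, and the co-chaperones Fes1A (AT3G09350) and Hop3 (AT4G12400), both partners of HSP70, rose by 3.63 and 3.51. Among the largest falls of genes with a symbol were the serine carboxypeptidase-like gene scpl33 (AT3G17180) at -4.01 (SE 0.18, adjusted p = 1.27e-07, a fall to 2.49, below the first quartiles of the arrays at 3.06 to 3.18), the subtilase SBT4.12 (AT5G59090) at -2.96, and XTH21 (AT2G18800), a xyloglucan endotransglucosylase/hydrolase that remodels cell walls, at -2.73. In all, 2965 genes (17.9%) passed, of which 1380 rose and 1585 fell.

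In the list of antioxidant enzymes and oxidative stress markers (below, the antioxidant list), 3 of 4 measured genes rose with arsenate and none fell (median 1.17). Adjusted over the list alone the counts were the same (3 and 0). The members that rose were UPOX, the glutathione reductase GR1 (AT3G24170) at 1.43 (SE 0.14, adjusted p = 3.20e-05), and CCS (AT1G12520), the copper chaperone for superoxide dismutase, at 0.90 (SE 0.19, adjusted p = 0.00602). The set test gave adjusted p = 0.000619, and adjusted p = 0.0737 with an estimated correlation. The 8 measured glutathione S-transferases went both ways, with 2 that rose, 3 that fell and 3 that did not pass (4 and 4 adjusted over the list alone, set test adjusted p = 0.707). GSTU25 and GSTU22 (AT1G78340, 3.05, SE 0.28, adjusted p = 2.17e-05) rose, whereas GSTU26 (AT1G17190) fell by 2.80 (SE 0.42, adjusted p = 0.000582) and GSTU20 and GSTU28 each fell by 1.45. All 3 measured root hair genes fell, XTH26 (AT4G28850) by 2.12 (SE 0.40, adjusted p = 0.00301), and the root hair expansins EXPA18 (AT1G62980) by 1.21 (adjusted p = 0.0258) and EXPA7 (AT1G12560) by 0.98 (adjusted p = 0.0135). Adjusted over the list alone 3 fell as well, and the set test gave adjusted p = 0.0130 (median -1.21), but adjusted p = 0.307 with an estimated correlation. Of the 5 iron deficiency genes, the transcription factors BHLH101 (AT5G04150, 1.59, SE 0.34, adjusted p = 0.00643) and PYE (0.70, adjusted p = 0.0294) rose and 3 did not pass, with 3 rising and 1 falling when adjusted over the list alone (set test adjusted p = 0.523). With the arrays compared alone S8H (1.07) rose (adjusted p = 0.0155) and IMA2 (-1.18) fell (0.0301), the latter also with array weights (0.0173).

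**Figure D2:**
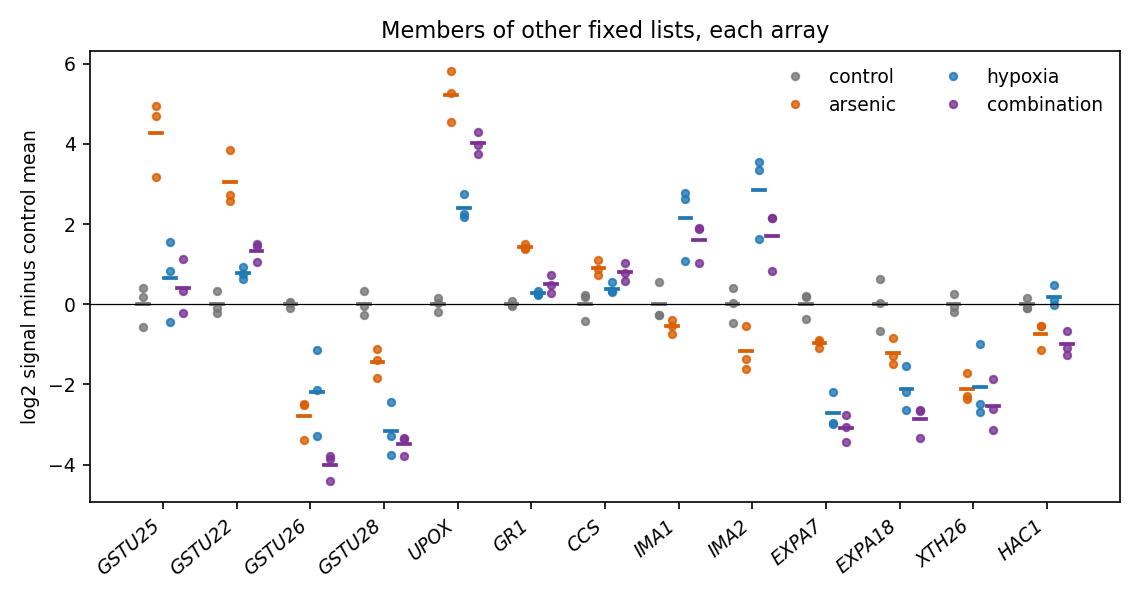
Log2 signal of 13 named genes minus the control mean of each gene (vertical axis), with a point for every array and a short bar for the mean of the 3 arrays of a group. UPOX lies at 5.21, 2.39 and 4.01 in arsenic, hypoxia and combination, whereas GSTU25 lies at 4.27 in arsenic and at 0.64 and 0.41 in hypoxia and combination.

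The nitrate transporter gene NRT2.5 (AT1G12940), the one nitrogen gene measured, rose by 2.2 with arsenate (SE 0.40, adjusted p = 0.00222). In the sulfate and glutathione list, the sulfur deficiency marker SDI2 (AT1G04770) rose by 1.45 and the sulfite reductase gene SIR (AT5G04590) fell by 0.77, and 2 members did not pass (2 rose and 1 fell adjusted over the list alone, set test adjusted p = 0.532). HAC1 (AT2G21045), the arsenate reductase and the one measured gene of arsenic handling, fell by 0.74 (SE 0.21, adjusted p = 0.0266). Of the 2 ethylene genes, RTE1 rose by 0.91 (adjusted p = 0.00215) and EIN3 did not pass (-0.11). The xylan synthesis gene GUT2 of the xylem list fell by 0.73 (SE 0.16, adjusted p = 0.00820). In the core hypoxia list, 1 of 9 rose (AlaAT1, 0.58, adjusted p = 0.0290), 1 fell (HUP54, -0.63, adjusted p = 0.00431) and 7 did not pass, with the same counts adjusted over the list alone (set test adjusted p = 0.629). None of the 4 abscisic acid genes passed in any of the 6 comparisons, over all genes or adjusted over the list alone (set test adjusted p = 0.532 with arsenate). LTI30 of that list, at 1.59 with arsenate (adjusted p = 0.123), did pass with a replicate block (0.0199), with array weights (0.0187) and without control 1 (0.00648). PDF1.2 of the jasmonate list (-0.07), ATHSP22.0 of the chaperone list (-0.13) and the reference gene TIP41 (0.18) did not pass.

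Of the 29 symbol families, 6 passed the set test with arsenate and none did with an estimated correlation. In the xyloglucan endotransglucosylase/hydrolase family, which shares XTH26 with the root hair list, 5 of 9 genes fell and none rose (8 fell adjusted over the list alone, median -1.20, adjusted p = 9.56e-05, and adjusted p = 0.308 with an estimated correlation). Of the 23 trichome birefringence-like genes, which act in wall polysaccharide acetylation, 7 fell and none rose (10 fell and 1 rose adjusted over the list alone, adjusted p = 0.0152, and adjusted p = 0.374 with an estimated correlation).

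The number of genes past the threshold was 1889 without arsenic array 3 and 1947 without control array 2, and with every array re-centred on its median 1803 rose and 1228 fell, so that the larger side was the rises, as it was with quantile normalization again (1586 and 1450). Leaving out 1 array lowers the number of arrays. The change of HAC1 was -0.545 without arsenic 1 and -0.784, -0.783 and -0.659 without controls 1, 2 and 3. Calls lost in this way included those of HAC1 (adjusted p = 0.113 without arsenic 1, and 0.0540, 0.0595 and 0.0961 without controls 1, 2 and 3), EXPA7 (0.0598 without control 2 and 0.0544 without control 3), EXPA18 (0.0756 and 0.109 without controls 2 and 3, 0.0958 and 0.0699 without arsenic 1 and 2) and AlaAT1 (0.0648, 0.0594 and 0.102 without controls 1, 2 and 3, 0.0667 and 0.122 without arsenic 1 and 3). PSAN of the green tissue list fell by 0.76 (adjusted p = 0.0497, and 0.115 and 0.179 without controls 2 and 3, 0.151, 0.0812 and 0.106 without arsenic 1, 2 and 3, 0.0562 with a replicate block, 0.0865 with re-centred arrays, 0.0509 with quantile normalization again and 0.0506 with trend and robust). CML38 (-1.73) passed without control 3 (adjusted p = 0.0349) and with array weights (0.0403). Re-centring raises changes against control, since the control medians lay 0.0760 to 0.109 above the mean of the 12 medians, and the largest shift between group means was 0.139.

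Hypoxia alone was compared with the control to show what low oxygen did without arsenate. All 9 measured genes of the core hypoxia response rose, and all 9 rose adjusted over the list alone (median 3.51). HUP9 (AT5G10040), a hypoxia-induced gene, rose 284-fold (8.15, SE 0.29, adjusted p = 3.62e-09), and HUP26 (AT3G03270) and HUP29 (AT4G24110), of the same group of hypoxia-induced unknown proteins, rose by 4.47 (SE 0.17, adjusted p = 5.12e-09) and 4.30 (SE 0.48, adjusted p = 4.84e-05). Genes of fermentation were in the list, with pyruvate decarboxylase PDC2 (AT5G54960) at 2.2, alanine aminotransferase AlaAT1 (AT1G17290) at 2.08 and lactate dehydrogenase LDH1 (AT4G17260) at 1.78. The set test gave adjusted p = 4.16e-12, and adjusted p = 0.00133 with an estimated correlation. In all, 4060 genes (24.5%) passed, of which 1791 rose and 2269 fell.

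**Figure D3:**
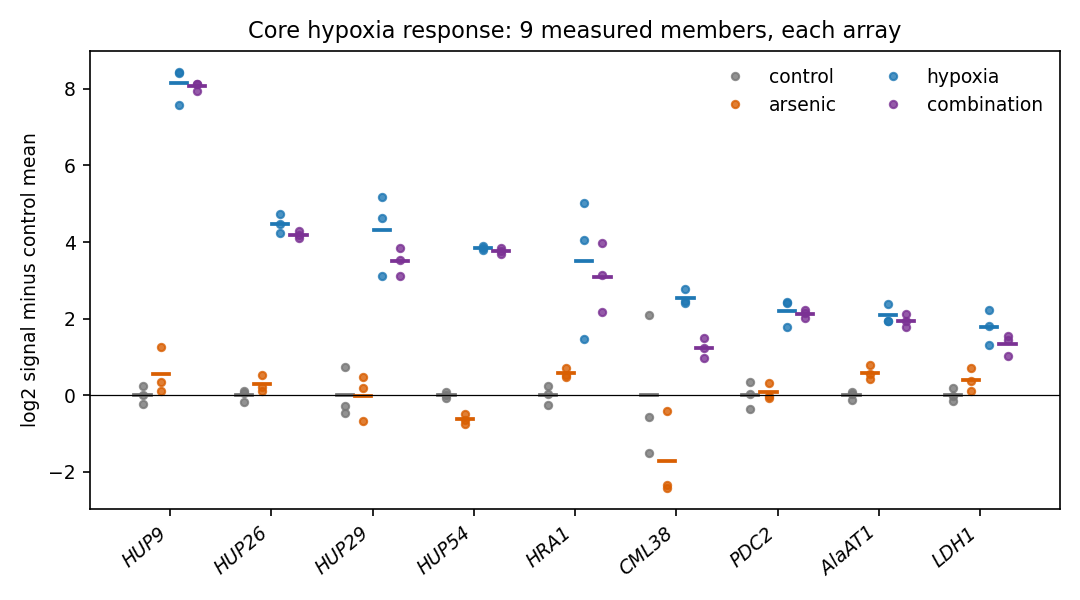
Log2 signal of the 9 measured core hypoxia genes minus the control mean of each gene (vertical axis), with a point for every array and a short bar for the mean of the 3 arrays of a group. HUP9 lies at 8.15 in hypoxia and 8.07 in the combination, and at 0.56 with arsenic alone.

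Outside that list, the largest rises under hypoxia among genes with a symbol were the beta-glucosidases BGLU31 (AT5G24540, 4.77, SE 0.62, adjusted p = 0.000146) and BGLU32 (AT5G24550, 3.96), close paralogs whose probes can cross-hybridise, the cell wall peroxidase PRX52 (AT5G05340, 4.53), and ICL (AT3G21720), the isocitrate lyase of the glyoxylate cycle (4.08, SE 0.34, adjusted p = 5.23e-06). The largest falls among genes with a symbol were the beta-tubulin TUB1 (AT1G75780, -4.18, SE 0.40, adjusted p = 1.40e-05), scpl33 (-3.87, a fall to below the first quartiles of the arrays at 3.06 to 3.18), the beta-glucosidase BGLU21 (AT1G66270, -3.55) and the hydroxyproline-rich glycoprotein HRGP1 (AT3G54590, -3.53).

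Of the 5 iron deficiency genes, 4 rose under hypoxia, none fell and 1 did not pass, with the same counts adjusted over the list alone (median 1.91). The small peptides IMA2 (AT1G47395) and IMA1 (AT1G47400), which promote iron uptake, rose by 2.84 (SE 0.49, adjusted p = 0.00124) and 2.16 (SE 0.40, adjusted p = 0.00177), and S8H (AT3G12900), which makes the iron-mobilising coumarin fraxetin, rose by 1.91. The set test gave adjusted p = 0.00181, and adjusted p = 0.0324 with an estimated correlation. All 3 root hair genes fell, and did so adjusted over the list alone, with EXPA7 at -2.72 (SE 0.24, adjusted p = 8.08e-06), EXPA18 at -2.13 and XTH26 at -2.06 (set test adjusted p = 0.000958, and adjusted p = 0.0948 with an estimated correlation). Of the glutathione S-transferases, 1 rose, 4 fell and 3 did not pass (2 and 4 adjusted over the list alone, set test adjusted p = 0.197), with GSTU28 (AT1G53680) at -3.17 (SE 0.30, adjusted p = 1.41e-05). GSTU25 did not pass (0.64). UPOX, a protein induced by oxidative stress, was the 1 gene of 4 in the antioxidant list that rose (2.39, SE 0.28, adjusted p = 6.35e-05), also adjusted over the list alone (set test adjusted p = 0.0798). GR1 passed with re-centred arrays (adjusted p = 0.0451). Without hypoxia array 2, the set tests of the glutathione S-transferases and of the antioxidant list each passed (adjusted p = 0.0482).

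NRT2.5 rose by 2.18 under hypoxia (SE 0.40, adjusted p = 0.00176). SDI2 rose by 1.15 and SIR fell by 0.97, as the 1 gene up and 1 down of the 4 in the sulfate and glutathione list, over all genes and adjusted over the list alone (set test adjusted p = 0.989). HAC1 did not pass (0.18, adjusted p = 0.558), nor did TIP41 (0.01) or PDF1.2 (-0.17), and the abscisic acid list, with a median of 0.02 and a mean of -0.03, gave a set test adjusted p = 0.989. GUT2 fell by 0.65 (adjusted p = 0.0120, and 0.0606 without control 2). Of the 29 families, 5 passed the set test and none did with an estimated correlation. In the xyloglucan endotransglucosylase/hydrolase family 1 gene rose and 8 of 9 fell, also adjusted over the list alone (median -1.57, adjusted p = 6.06e-05, and adjusted p = 0.140 with an estimated correlation). Of the trichome birefringence-like genes 9 of 23 fell and none rose (10 fell adjusted over the list alone, adjusted p = 0.00590, and adjusted p = 0.211 with an estimated correlation).

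With arrays re-centred, 3153 genes rose and 1834 fell under hypoxia, so that the larger side was again the rises. The median change over all genes was already 0.07 with the deposited values, and re-centring moves changes against control further up. Small rises passed narrowly for EIN3 (0.49), whose call was lost without any array but hypoxia 2 (adjusted p = 0.0691 to 0.0956) and with quantile normalization again (0.0522), for RCA of the green tissue list (0.63; adjusted p = 0.101, 0.0745, 0.0741 and 0.0758 without control 1, control 3, hypoxia 2 and hypoxia 3) and for ATHSP22.0 (0.49; adjusted p = 0.0680, 0.0929 and 0.0692 without control 1, control 2 and hypoxia 3, and 0.0809 with quantile normalization again).

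The combination was compared with the control to show the state of roots under both treatments. The core hypoxia genes stood nearly as high as under hypoxia alone, with HUP9 at 8.07 (SE 0.29, adjusted p = 4.07e-09), HUP26 at 4.19 and HUP54 (AT4G27450) at 3.77. Of the 9 measured, 8 rose, none fell and CML38 did not pass (1.22), with the same counts adjusted over the list alone (median 3.1, set test adjusted p = 1.68e-09, and adjusted p = 0.00316 with an estimated correlation). ICL rose 25.9-fold (4.69, SE 0.34, adjusted p = 1.21e-06), the U-box ubiquitin ligase gene PUB54 (AT1G01680) rose by 3.63, and GH3.3 (AT2G23170), an enzyme that conjugates auxin to amino acids, rose by 3.28. BGLU21 fell 55.5-fold (-5.79, SE 0.53, adjusted p = 6.68e-06), HRGP1 fell by 5.04 and TUB1 by 4.56. In all, 4578 genes (27.7%) passed, of which 2158 rose and 2420 fell.

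In the combination UPOX rose by 4.01 (SE 0.28, adjusted p = 8.39e-07), CCS by 0.80 and GR1 by 0.50 (adjusted p = 0.0174). With these, 3 of the 4 genes of the antioxidant list rose and none fell, also adjusted over the list alone (set test adjusted p = 0.0114, and adjusted p = 0.0807 with an estimated correlation). GSTU25, with its 19.3-fold rise under arsenate alone, did not pass (0.41, SE 0.54, adjusted p = 0.613). Of the glutathione S-transferases, 2 rose, 4 fell and 2 did not pass (2 and 4 adjusted over the list alone as well, set test adjusted p = 0.110), with GSTU26 at -4.02 (SE 0.42, adjusted p = 1.72e-05), GSTU28 at -3.50 and GSTU20 (AT1G78370) at -3.11. The 3 root hair genes all fell, also adjusted over the list alone, with EXPA7 at -3.09 (SE 0.24, adjusted p = 1.95e-06), EXPA18 at -2.88 and XTH26 at -2.54 (set test adjusted p = 0.000393, and adjusted p = 0.0807 with an estimated correlation). Of the iron deficiency genes 3 of 5 rose and none fell, also adjusted over the list alone, namely IMA2 (1.70, adjusted p = 0.0212), IMA1 (1.60, adjusted p = 0.00917) and PYE (AT3G47640, 1.15, SE 0.20, adjusted p = 0.000956). The set test gave adjusted p = 0.0351, and adjusted p = 0.0807 with an estimated correlation. HAC1 fell by 1.00 (SE 0.21, adjusted p = 0.00307).

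SIR fell by 1.61 and SDI2 rose by 1.13 in the combination, the 1 fall and 1 rise among the 4 genes of the sulfate and glutathione list (2 rose and 1 fell adjusted over the list alone). That list had a median of 0.49 and a mean of 0.23 while the set test pointed down (adjusted p = 0.985). Its member BGLU28 (AT2G44460) missed the threshold at 1.56 (adjusted p = 0.0528) but passed with a replicate block (0.0489), re-centred arrays (0.0311), the dimmest genes left out (0.0447), trend and robust (0.0438) and array weights (0.0130), and without combination 3 (0.0208). GUT2 fell by 1.02, and the abscisic acid list, with a median of 0.01 and a mean of -0.01, gave a set test adjusted p = 0.985. TIP41 did not pass over all genes (0.28, adjusted p = 0.110), but passed as a list of 1, where nothing is adjusted, and with re-centred arrays (0.42, adjusted p = 0.0249). RCA (0.41, adjusted p = 0.130) passed with re-centred arrays (0.0445) and without combination 3 (0.0223). Of the 29 families, 6 passed and none did with an estimated correlation. They included the xyloglucan endotransglucosylase/hydrolases (1 rose and 8 of 9 fell, also adjusted over the list alone, median -2.24, adjusted p = 7.39e-06, and adjusted p = 0.0746 with an estimated correlation), the trichome birefringence-like genes (12 of 23 fell and none rose, 13 fell adjusted over the list alone, adjusted p = 9.08e-05, and adjusted p = 0.0746 with an estimated correlation) and the serine carboxypeptidase-like genes (2 rose and 14 of 32 fell, also adjusted over the list alone, adjusted p = 0.000243, and adjusted p = 0.0550 with an estimated correlation).

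The larger side was the rises with arrays re-centred (3645 rose and 1971 fell), with quantile normalization again (2480 and 2337) and with array weights (3186 and 2920). The median change over all genes was 0.09 with the deposited values, before re-centring raised it. On re-centring the iron set test was lost (adjusted p = 0.0583), as it was without control 3 (0.0516) or combination 3 (0.0876). PSAN fell by 0.72 (adjusted p = 0.0448), a call lost with the arrays compared alone (0.0819), a replicate block (0.0509) and re-centring (0.0885). Without control 2, control 3 and combination 3 its change was -0.726, -0.550 and -0.427 (adjusted p = 0.0980, 0.161 and 0.173). Its call was thus among those lost with 1 array left out. Others were GR1 (adjusted p = 0.0540, 0.0616 and 0.0745 without control 1, control 2 and combination 3), IMA2 (0.0848, 0.0507, 0.0837 and 0.0761 without control 2, control 3, combination 2 and combination 3) and NRT2.5, which rose by 1.18 (adjusted p = 0.0433, and 0.0965, 0.129, 0.0608, 0.153 and 0.0879 without controls 1, 2 and 3, combination 1 and combination 2).

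Changes of the single treatments against the same 3 controls were compared across genes. Of the genes that passed with arsenate, 45% passed in the same direction under hypoxia (451 rose and 882 fell in both, against 149 and 217 expected from the counts alone) and 93 passed in opposite directions. Both arsenate and hypoxia lowered scpl33, XTH21 and GSTU26, and both raised UPOX, NRT2.5 and SDI2. Of the genes that passed with arsenate 68.6% passed the same way in the combination (874 rose and 1159 fell, against 180 and 232 expected), and of those that passed under hypoxia 67.6% did (1054 and 1690, against 234 and 332). The changes with arsenate and under hypoxia correlated with those in the combination at r = 0.717 and 0.864. These also share the controls, which alone gave a simulated r = 0.501 for each. Their covariances were 0.343 and 0.477, against 0.0246 and 0.0247 in the simulation. The 2 single changes correlated across genes at r = 0.541, but sharing the controls alone gave r = 0.50 in simulated groups with no change. The covariance was 0.231 against 0.0246 in the simulation. The simulation called no gene in both, which was nearly fixed in advance because no simulated group changed. The expected counts ignore the shared controls too, so how many of the overlapping calls come from control error is not known. The covariances argue against control error as the main source of the shared change, since each was far above its simulated value.

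The combination was compared with arsenic alone to show what hypoxia did in roots that also received arsenate. All 9 core hypoxia genes rose, also adjusted over the list alone (median 2.96), with HUP9 at 7.51 (SE 0.29, adjusted p = 1.33e-08) and HUP54 at 4.40 (SE 0.13, adjusted p = 5.00e-10). The set test gave adjusted p = 6.56e-15, and adjusted p = 0.000622 with an estimated correlation. ICL rose by 4.56 (SE 0.34, adjusted p = 6.16e-06), PRX52 by 3.31, and ATC (AT2G27550), a homologue of the flowering regulator CENTRORADIALIS, by 2.75. BGLU21 fell by 4.24, HRGP1 by 3.96, GSTU25 by 3.86 (SE 0.54, adjusted p = 0.000569) and the endoglucanase GH9C1 (AT1G48930) by 3.48. In all, 1986 genes (12%) passed, of which 882 rose and 1104 fell.

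Of the glutathione S-transferases, 4 of 8 fell and none rose when hypoxia was added to arsenate (5 fell adjusted over the list alone, median -1.44). GSTU25, GSTU28 (-2.05), GSTU22 (-1.72) and GSTU20 (-1.65) were the 4, and the set test gave adjusted p = 4.09e-05, and adjusted p = 0.0900 with an estimated correlation. GR1 fell by 0.93 (SE 0.14, adjusted p = 0.000870) and UPOX by 1.2 (adjusted p = 0.0135), the 2 of 4 genes of the antioxidant list that passed, also adjusted over the list alone (set test adjusted p = 0.0733). IMA2 rose by 2.88 (SE 0.49, adjusted p = 0.00217) and IMA1 by 2.15, while BHLH101 fell by 1.33 (adjusted p = 0.0245), so that the iron list had 2 up, 1 down and 2 that did not pass, also adjusted over the list alone (set test adjusted p = 0.172, but 0.0271 with a median of 1.30 when the dimmest genes were left out). EXPA7 fell by 2.11 and EXPA18 by 1.67, 2 of the 3 root hair genes, also adjusted over the list alone (set test adjusted p = 0.00286, and adjusted p = 0.145 with an estimated correlation). SIR fell by 0.85 as the 1 gene of 4 in the sulfate list (also adjusted over the list alone, set test adjusted p = 0.144), and RTE1 fell by 0.90 (EIN3, at 0.35, rose adjusted over the ethylene list alone). NRT2.5 (-1.02) fell as a list of 1. HAC1 (-0.26), GUT2 (-0.29), TIP41 (0.10), and RCA (0.32) and PSAN (0.04) of the green tissue list did not pass. Of the families, 4 passed and none did with an estimated correlation.

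The number of genes was 1065 without arsenic 3 and 1177 without combination 2, and with arrays re-centred 1043 rose and 991 fell. Leaving out arsenic 3 ended the call of UPOX (adjusted p = 0.0618), and the rise of CML38 (2.96) was lost without any array but arsenic 1 (adjusted p = 0.0501 to 0.0853). The set test of the antioxidant list passed without arsenic 2 (adjusted p = 0.0423) or combination 3 (0.0456). LTI30 (-1.76) passed with the arrays compared alone (adjusted p = 0.00246), a replicate block (0.0162) and array weights (0.0340), and NRT2.5 without arsenic 2 (0.0128) and with array weights (0.0325).

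The combination was compared with hypoxia alone to show what arsenate did in roots that were also hypoxic. UPOX rose by 1.62 (SE 0.28, adjusted p = 0.00966). BAT1 (AT4G31910), an acyltransferase linked to brassinosteroids, fell by 2.34 (SE 0.30, adjusted p = 0.00355), the subtilase ATSBT5.2 (AT1G20160) fell by 2.17 (adjusted p = 0.00484) and BGLU32 fell by 2.15 (adjusted p = 0.00484). Rises among genes with a symbol included NRPC1 (AT5G60040), the largest subunit of RNA polymerase III, at 1.56 (adjusted p = 0.0180), and the chromatin remodelling gene CHR23 (AT5G19310) at 1.26 (adjusted p = 0.0232). HAC1 fell by 1.19 (SE 0.21, adjusted p = 0.0110) and GSTU26 by 1.83 (adjusted p = 0.0335). In all, 573 genes passed, of which 311 rose and 262 fell, but of those changed at least 2-fold 86 rose and 168 fell.

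GSTU25 did not pass when arsenate was added to hypoxia (-0.23, SE 0.54, adjusted p = 0.860), and GSTU26 was the 1 glutathione S-transferase of 8 that did (1 fell adjusted over the list alone, set test adjusted p = 0.255). UPOX was the 1 gene of 4 in the antioxidant list that passed (1 rose adjusted over the list alone, set test adjusted p = 0.0501). No member passed in the core hypoxia list of 9 (median -0.28, set test adjusted p = 0.0998), the iron list of 5 (0.0998), the root hair list of 3 (0.128) or the sulfate list of 4 (0.632, with SIR falling when adjusted over the list alone, and a median of -0.05 beside a mean of 0.05). SIR (-0.65, adjusted p = 0.0513) passed with quantile normalization again (0.0494), the dimmest genes left out (0.0342), trend and robust (0.0235) and array weights (0.0336), and without combination 1 (0.0485). GSTU20 (0.0344) and IMA2 (0.0316) passed without hypoxia 1. As lists of 1, TIP41 (0.27) rose and NRT2.5, ATHSP22.0 (-0.42) and GUT2 (-0.37) fell, and none of them passed over all genes. Of the families, 5 passed and none did with an estimated correlation. Of the 63 genes encoded in the plastid genome 1 fell and none rose (none passed adjusted over the list alone, median -0.23, adjusted p = 2.18e-06, and adjusted p = 0.538 with an estimated correlation).

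The fit of all arrays shares 1 spread, and the median SD over genes was 0.232 in hypoxia and 0.207 in the combination, against 0.166 in control and 0.183 in arsenic. Its adjusted p for this comparison thus drew on less variable groups. The count of 573 genes rested on the setting and on single arrays, with 30 genes (11 rose and 19 fell) when the spread was taken from the arrays compared alone. It was 888 (442 rose and 446 fell), 184 (85 and 99), 1000 (631 and 369), 101 (48 and 53) and 194 (97 and 97) without hypoxia 1, hypoxia 2, combination 1, combination 2 and combination 3. With the arrays compared alone the calls of NRPC1, CHR23, HAC1, GSTU26 and ATSBT5.2 were lost (adjusted p = 0.129, 0.135, 0.0757, 0.147 and 0.0726), as were those of NRPC1 (0.0813 and 0.0874), CHR23 (0.0990 and 0.119), HAC1 (0.0524 and 0.0705) and GSTU26 (0.108 and 0.104) without hypoxia 2 and without combination 2, and those of CHR23 (0.0902) and GSTU26 (0.123) without combination 3. Set tests passed without hypoxia 1 for the core hypoxia, antioxidant and iron lists (each adjusted p = 0.0320), without combination 1 (0.0417) or combination 2 (0.0499) for the antioxidant list, without combination 3 for the iron list (0.0391), and with a replicate block for the antioxidant list (0.0357).

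The interaction asked whether the combined change differed from the sum of the single changes on the log2 scale. OCT1 (AT1G73220), an organic cation and carnitine transporter, rose with arsenate from 3.57 to 6.82 but stood at 3.95 under hypoxia and 3.54 in the combination, an interaction of -3.67 (SE 0.20, adjusted p = 3.03e-06). GSTU25 had group means of 3.32, 7.59, 3.96 and 3.73 in control, arsenic, hypoxia and combination (-4.50, SE 0.77, adjusted p = 0.00850). UPOX fell short of the sum by 3.59 on the log2 scale, its interaction being -3.59 (SE 0.39, adjusted p = 0.000685), and GSTU22 (-2.49), GR1 (-1.20), the glucosyltransferase UGT87A2 (AT2G30140, -3.25) and NRT2.5 (-3.20) were negative too. Of the genes named for positive values, scpl33 was at 6.50 in control and at 2.49, 2.63 and 2.41 in the treated groups (3.79, SE 0.25, adjusted p = 1.75e-05), ATPC1 (AT4G04640) at 4.46, 2.37, 2.57 and 2.41 (1.93), XTH21 at 7.35, 4.61, 4.00 and 3.55 (2.29) and XTH16 (AT3G23730) at 5.22, 2.90, 2.27 and 1.96 (2.01). The treated means of scpl33, ATPC1 and XTH16 lay below the first quartiles of the arrays (3.06 to 3.18). For scpl33 and XTH16, the sum of the single changes would put the combination below the lowest values of the arrays (0.484 to 0.721). Their positive interactions thus do not show that the treatments failed to add. For ATPC1 and XTH21 that sum would lie below the first quartiles, and whether a fall that far could show was not tested. In all, 457 genes passed, of which 221 were positive and 236 negative.

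Of these 457 genes, 453 had an interaction opposite in sign to their change with arsenate, which the contrast in part builds in because it subtracts that change. Those called the same way with arsenate and under hypoxia and opposite to both in the interaction numbered 327, and 18 passed with neither treatment. In the antioxidant list 2 of 4 were negative and none positive, also adjusted over the list alone (median -0.85, set test adjusted p = 0.00251, and adjusted p = 0.0857 with an estimated correlation). No iron deficiency gene passed over all genes, while 3 of 5 were negative adjusted over the list alone (median -1.04, set test adjusted p = 0.0224, and adjusted p = 0.0857 with an estimated correlation). GSTU25 and GSTU22 were the 2 glutathione S-transferases of 8 that passed, also adjusted over the list alone (set test adjusted p = 0.20). SDI2 of the sulfate list was at -1.47 (adjusted p = 0.0456) and the other 3 did not pass (1 fell adjusted over the list alone, set test adjusted p = 0.20). HAC1 did not pass (-0.44), nor did any of the 9 core hypoxia genes (1 rose and 1 fell adjusted over the list alone, set test adjusted p = 0.0917) or the 3 root hair genes (1 rose adjusted over the list alone, 0.0917). In the xyloglucan endotransglucosylase/hydrolase family 2 of 9 were positive and none negative (5 positive adjusted over the list alone, median 1.01, adjusted p = 0.00432, and adjusted p = 0.605 with an estimated correlation), the 1 family of 29 that passed.

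**Figure D4:**
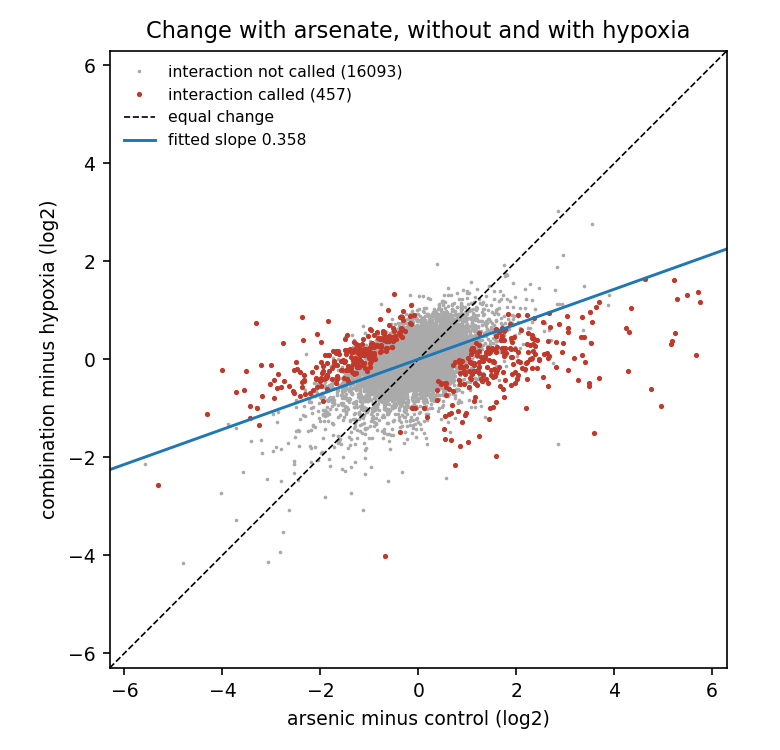
Log2 change with arsenate in roots that were not hypoxic (horizontal axis, arsenic minus control) against the change with arsenate under hypoxia (vertical axis, combination minus hypoxia), with a point for each of 16550 genes. The 457 genes with an interaction are red, the dashed line marks equal change, and the blue line has the slope of 0.358 fitted over all genes.

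Across all genes, the measured log2 change with arsenate was smaller in hypoxic roots. That does not show that arsenate acted less there, since a floor and genes already changed by hypoxia are not excluded, as described further below. Per unit of change with arsenate alone, the change with arsenate under hypoxia was 0.358 (jackknife SE 0.0710) across genes, from 0.308 without hypoxia 2 to 0.398 without hypoxia 1, and the comparisons shared no array. Of the 2965 genes that passed with arsenate alone, 81.0% kept their sign under hypoxia and 336 passed there in the same direction. In the same way the change with hypoxia was 0.564 (jackknife SE 0.0732) with arsenate per unit without it, 84.5% of 4060 genes kept their sign and 1211 passed in both.

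The interaction count was 213, 252, 255, 225, 252 and 278 genes without control 2, control 3, arsenic 1, arsenic 3, combination 2 and combination 3, and with re-centred arrays 157 were positive and 270 negative. More were positive than negative with the dimmest genes left out (265 and 253), with array weights (463 and 423) and without hypoxia 2 (217 and 203). BHLH101 (-1.74) passed with a replicate block (adjusted p = 0.0340) and without arsenic 1 (0.0345), S8H (-2.05) without hypoxia 3 (0.0197) and XTH26 without hypoxia 2 (0.0234). Set tests passed for the core hypoxia list without control 1 (adjusted p = 0.0332) or hypoxia 1 (0.0126), for the root hair list without control 1 (0.0339), hypoxia 2 (0.0108) or combination 2 (0.0280) and for the abscisic acid list without control 1 (0.0339). That of the iron list was lost without combination 1 (0.118) and without the dimmest genes (0.0862), that of the xyloglucan family was lost without the dimmest genes (0.0885), and the call of SDI2 was lost without any array but hypoxia 1 and combination 3 (0.0547 to 0.126).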

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

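The slopes with their tests and simulation, the tests of the plastid-encoded and other symbol families beyond the set test, and the tests of array 1 of the hypoxia group were chosen only after the result was seen, and the others before. An effect of arsenate that differed between roots with and without hypoxia, by the test of the interaction, singled out 457 genes. Of 100 splits of the 12 arrays, the real one included, 3 gave as many genes, with 2687 in the highest other, but chance cannot be excluded by them, since most splits mix treatments and so widen the spread. Splits that mix treatments can also set most arrays of 1 treatment against the rest, so that the contrast takes up the change with that treatment. The make-up of the split with 2687 was not examined. The count was 213 without control 2, 252 without control 3, 255 without arsenic 1, 225 without arsenic 3, 252 without combination 2 and 278 without combination 3. Among the named genes that passed, scpl33 (3.79), XTH21 (2.29), XTH16 (2.01) and ATPC1 (1.93) lay above the sum of the single changes, and GSTU25 (-4.50), OCT1 (-3.67), UPOX (-3.59), UGT87A2 (-3.25), NRT2.5 (-3.20), GSTU22 (-2.49), SDI2 (-1.47) and GR1 (-1.20) below it. The call of SDI2 was lost without any array but hypoxia 1 and combination 3 (adjusted p = 0.0547 to 0.126). In scpl33, ATPC1 and XTH16 the treated groups stood between 1.96 and 2.90, below the first quartiles of the arrays (3.06 to 3.18). For scpl33 and XTH16 the sum of the single changes lay below the lowest values of the arrays (0.484 to 0.721). Their positive values thus do not show that the treatments failed to add. For ATPC1 and XTH21 that sum lay below the first quartiles, and whether a fall that far could show was not tested. Among the fixed lists and symbol families, the set tests that gave a difference were those of the antioxidant list (median -0.85), the iron deficiency list (-1.04) and the xyloglucan endotransglucosylase/hydrolase family (1.01), and none held with an estimated correlation (adjusted p = 0.0857, 0.0857 and 0.605). Lists formed later from single loci are described further below. The iron call was also lost without combination 1 (adjusted p = 0.118) and with the dimmest 33.3% of genes left out (0.0862).

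Rows with no gene name of their own, which the comparisons of genes left out, also differed from the control arrays. Of 21686 such rows, 2639 passed with arsenic, 4006 under hypoxia and 4362 in the combination.

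The smaller change with arsenate under hypoxia (slope 0.358, jackknife SE 0.0710) was weighed against technical sources. A single array is argued against, since the highest slope with 1 array left out was 0.398. Compression in genes of low or high mean signal is argued against as well, since the slope was 0.343 (jackknife SE 0.0760) among genes of middle mean. The dimmest and brightest 33.3% were left out there by their mean over all arrays. A gene that fell to the floor in treated groups can keep a middle mean, so a floor that hides a second fall is not excluded. The share of the pattern that lies in genes which hypoxia had already changed cannot be told apart from an effect on all genes, because the slope among the 5615 genes that hypoxia alone moved by under 0.2 was 0.685 with a jackknife SE of 0.150, too wide to exclude 0.9. Choosing genes by that change reuses arrays and raises the slope, to 0.452 (0.428 to 0.470 over 20 simulations) for a common slope of 0.358. Among genes moved by 0.2 to 0.5, 0.5 to 1 and 1 or more (1669 genes), the slopes were 0.548, 0.306 and 0.213. The simulated ranges were 0.387 to 0.425, 0.314 to 0.346 and 0.306 to 0.342 (mean 0.322), and each slope, like the 0.685, lay outside its range. The simulated genes varied independently, so these ranges leave out error that the genes of an array share. It remains a hypothesis that arsenate and hypoxia may act on a shared set of genes with little room for a second change, beside an effect of hypoxia on arsenate itself, which no measurement here addresses.

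The lower signal of the 63 plastid-encoded genes in the combination than under hypoxia (median -0.23, set test adjusted p = 2.18e-06, and adjusted p = 0.538 with an estimated correlation) was weighed as well. Variation of plastid RNA between arrays of a group cannot be told apart from a change between groups, since the 0 of 9 pairs with the combination array at or above the hypoxia array restate the lower median, and the gap of 0.07 between the groups was narrower than the range of 0.33 within hypoxia and 0.15 within the combination. A single array could account for much of the pattern, since the highest median with 1 array left out was -0.0804, without hypoxia 3 (set test adjusted p = 0.0341), whose mean plastid signal was 10.44 against 10.11 in both other hypoxia arrays. Arsenic against control, which shares no array with this comparison, had 8 fallen and none risen, also adjusted over the list alone (median -0.23, adjusted p = 0.000750, and adjusted p = 0.911 with an estimated correlation), a call lost without control 1 (median -0.13, adjusted p = 0.128). The combination against control had 14 fallen and none risen (11 fallen adjusted over the list alone, median -0.15, adjusted p = 0.0310, and adjusted p = 0.928 with an estimated correlation), a call lost without control 1 (-0.08, 0.549) and combination 1 (-0.10, 0.123), with re-centred arrays (-0.01, 0.0647), with the dimmest genes left out (0.135) and with array weights (-0.10, 0.123), so that an effect of arsenate on plastid transcripts stays open.

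Hypoxia array 1 was closer to combination array 1 (r = 0.982) than to the other arrays of its own group (r = 0.973 and 0.972), and 2 explanations were weighed. Arsenate in the plants of hypoxia array 1, with an effect as strong as in the combination, is argued against. On the axis from the control mean (0) to the arsenic mean (1) it lay at 0.672, below the lowest combination array at 0.851. It was still the highest hypoxia array, with the others at 0.495 and 0.594, so a smaller exposure is not excluded. The axis also responds to hypoxia, so a position on it is not a measure of arsenate alone. Combination array 1 was the lowest of its group, and whether it was the odd array was not weighed. A deviation shared by the arrays numbered 1 is a candidate explanation, since their deviations from the group means correlated at 0.305 across genes, against at most 0.0915 for hypoxia and combination arrays with different numbers. The pair was picked for its high r, so this in part restates the pattern. Deviations from a mean of 3 also push pairs with different numbers down. Outside that pair, control 1 had 0.292 with hypoxia 1 and 0.168 with combination 1, and arsenic 1 had 0.0795 and 0.113. Hypoxia 3 and combination 3 had 0.292, but hypoxia 2 and combination 2 had -0.0789, and a common day or chamber is not in the labels. No biological explanation was tested.

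For the pairwise comparisons, the splits of 6 arrays are too few for a share under 0.05, with 1 of 10 splits giving as many genes in each. The real counts and highest other splits were 2965 and 0 for arsenic, 4060 and 0 for hypoxia and 4578 and 0 for the combination against control, 1986 and 0 for the combination against arsenic, and 573 and 35 for the combination against hypoxia.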

How the results depend on the processing

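The settings for the slopes and the lists formed from single loci were chosen after the data were seen, those for the symbol families after the annotation was read, and the others before. No gene or list changed direction past its threshold, though the larger side of a count turned in some settings, and the counts of genes stayed within 1.5 times of their values with the replicate block, re-centring, a second quantile normalization, the dimmest 33.3% left out, trend and robust, and the mean of all rows. With array weights, 4700 genes passed with arsenic against control, 3527 in the combination against arsenic and 886 in the interaction, and the cause was not tested. With only the arrays compared, 30 passed in the combination against hypoxia (11 rose and 19 fell), whereas 3597 passed in arsenic against control. The setting gives no value for the interaction, which uses all arrays. The median SD over genes was 0.232 in hypoxia and 0.207 in the combination, against 0.166 in control and 0.183 in arsenic. The fit of all arrays thus drew on less variable groups for the combination against hypoxia. Fewer arrays also leave fewer degrees of freedom, and these sources were not separated. Every row of the table, being more rows, gave 5113, 7517 and 8437 against control for arsenic, hypoxia and combination, and 3100 for the combination against arsenic. A change of at least 2-fold, a narrower criterion, left 1186, 1586 and 1947 against control, 917 against arsenic and 254 against hypoxia (86 rose and 168 fell). Leaving out 1 array, which lowers the number of arrays, gave 1889 to 2492 genes for arsenic, 2836 to 3664 for hypoxia and 3494 to 4151 for the combination against control. It gave 1065 to 1824 against arsenic, 101 to 1000 against hypoxia and 213 to 502 for the interaction, and the slopes ran from 0.308 to 0.398 and from 0.521 to 0.611. The low values came without arsenic 3 (1889, 1065), control 2 (2836, 3494, 213) and combination 2 (101), and those over 1.5 times away were also 1947 (control 2, arsenic), 1177 (combination 2, against arsenic), 888, 184, 1000 and 194 (hypoxia 1, hypoxia 2, combination 1, combination 3, against hypoxia) and 252, 255, 225, 252 and 278 (control 3, arsenic 1, arsenic 3, combination 2, combination 3, interaction).

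With 1 array left out, 1423 values of named genes stayed on their side of the threshold, 84 dropped below and 11 rose above it, and of fixed lists 275 stayed, 3 dropped and 16 rose. With an estimated correlation, 10 calls of fixed lists, 7 of added lists and 27 of families were lost. The replicate block gave 3067, 4169, 4690, 2061, 592 and 552 genes, and slopes of 0.351 and 0.556. Replicate numbers did not pair the arrays throughout, since of 18 pairs with the same number 6 correlated above 0.1 (-0.0789 to 0.305) and 6 of 12 arrays had their best partner under the same number. Rows with no gene of their own leave most members of the fixed lists unmeasured.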

Other observations

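Both lists below, and the tests of them, were chosen only after the results were seen. Small heat shock proteins, chaperones that hold unfolded proteins, are listed by locus code in the annotation, and 13 of 19 were measured. With arsenate 8 rose, 1 fell and 4 did not pass (8 and 1 adjusted over the list alone, median 1.74, set test adjusted p = 0.000152, and adjusted p = 0.194 with an estimated correlation), led by AT5G51440 at 5.75 (SE 0.37, adjusted p = 1.74e-06) and AT1G07400 at 5.71 (SE 0.58, adjusted p = 4.12e-05), while AT4G21870 fell by 1.51. Under hypoxia 5 rose, 2 fell and 6 did not pass (8 and 2 adjusted over the list alone, median 1.04, adjusted p = 0.0192, and adjusted p = 0.507 with an estimated correlation), a call lost without hypoxia 1 (median 0.48, adjusted p = 0.0665) and with re-centred arrays (0.0636). In the combination 6 rose, 2 fell and 5 did not pass (8 and 2 adjusted over the list alone, median 1.29, adjusted p = 0.00608, and adjusted p = 0.229 with an estimated correlation), with AT5G51440 at 4.81. Against arsenic alone AT5G37670 fell by 1.12 and 12 did not pass, also adjusted over the list alone (set test adjusted p = 0.0943), and against hypoxia none of 13 passed over all genes or adjusted over the list alone (median 0.29, adjusted p = 0.152), but the set test passed without hypoxia 1 (median 0.90, adjusted p = 3.76e-06), while the median was 0.10 without hypoxia 2 and -0.08 without hypoxia 3 (adjusted p = 0.815). In the interaction 3 fell and 10 did not pass (6 fell and 1 rose adjusted over the list alone, median -1.24, adjusted p = 9.55e-05, and adjusted p = 0.179 with an estimated correlation), and the median was -0.41 without hypoxia 1, with AT5G51440 at -4.58 (SE 0.53, adjusted p = 0.000965) and AT1G07400 at -4.34 (SE 0.82, adjusted p = 0.0139).

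Class III peroxidases, secreted enzymes that act on cell walls, had 64 of 73 loci measured. Under hypoxia 17 rose, 18 fell and 29 did not pass (18 and 19 adjusted over the list alone), with a median of 0.17, a mean of -0.09 and a set test that pointed down (adjusted p = 0.676). PRX52 rose by 4.53 (SE 0.57, adjusted p = 0.000116) and AT4G36430 by 2.46, while AT3G49960 fell by 3.73 and AT4G26010 by 3.66 (SE 0.35, adjusted p = 1.40e-05). In the combination 12 rose, 24 fell and 28 did not pass (12 and 24 adjusted over the list alone, median -0.06, but -0.30 without combination 1, -0.11 without combination 2 and 0.08 with re-centred arrays, adjusted p = 0.00167, and adjusted p = 0.229 with an estimated correlation), with AT5G19890 at -5.03 (SE 0.54, adjusted p = 2.12e-05) and AT4G26010 at -4.80. Against hypoxia alone none rose, 8 fell and 56 did not pass (17 fell adjusted over the list alone, median -0.40), with AT5G19890 at -4.01 (SE 0.54, adjusted p = 0.00389). The set test gave adjusted p = 5.52e-10, and adjusted p = 0.0275 with an estimated correlation. Both values are adjusted over the lists of this section alone, which were picked from these same data, so they give no independent support. Sets were not tested with the arrays compared alone. Against arsenic alone 6 rose, 19 fell and 39 did not pass (8 and 21 adjusted over the list alone, adjusted p = 0.000818, and adjusted p = 0.233 with an estimated correlation). With arsenate alone 5 rose, 14 fell and 45 did not pass (7 and 16 adjusted over the list alone, adjusted p = 0.0631), and the set test passed without control 3 (0.0334) and with re-centred (0.0269) or again quantile-normalized arrays (0.0469). In the interaction 1 was positive, 4 negative and 59 did not pass (3 and 11 adjusted over the list alone, adjusted p = 0.00392, and adjusted p = 0.189 with an estimated correlation).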
